A study of Mus musculus with 32 samples.

How the data were processed

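Gene expression was measured by polyA RNA sequencing in 32 muscle libraries from 16 mice, 4 mice of each of 4 genotypes. Myofibre-specific deletion of Acvr1b, of Tgfbr1 or of both was induced with tamoxifen at 6 weeks of age, and the left gastrocnemius medialis, a mainly fast muscle, and the left soleus, a mainly slow muscle, were taken 3 months later, per the labels' protocols. RNA was extracted with TRIzol, RIN values were above 7.7, and libraries were made with a KAPA mRNA HyperPrep kit, per the labels' protocols. Each of the 8 groups of genotype and muscle held 4 libraries, grouped by the tissue and genotype that the labels give, and the animal number in the labels joined the gastrocnemius and the soleus library of 1 mouse. The animal numbers of the 4 double-knockout mice lie apart from those of the 12 other mice.

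The single table used held estimated read counts per gene, made by the authors with featureCounts 2.0.1 on GRCm38 with Ensembl 102 gene models, per the file headers. Reads were assigned on the reverse strand (setting 2), and a read that aligned to several places was shared between them as a fraction, per the file headers, so that the deposited estimated counts need not be whole numbers. Genes with a near-identical copy therefore share reads. Of the genes tested in gastrocnemius, 39.8% had fractional counts in at least 16 of the 32 libraries. Among the genes named in the text these were Mettl7a3, Ccl21b, Myh7, Myh2, Myh4, Plin4, Amd1, Rps12 and Tnnt3 (32 libraries each), Lpl, Pfkfb3, Sms and Myh1 (31), Slc2a3 and Inhba (29), Uqcrh (28), Gadl1 and Ppargc1a (26), Myh11 (25), Actc1 and Mettl7a2 (24), Slc25a30 (23), Sphk1 (22), Actn3 (20), Gm49492 and Ddit4l (19), Tnnt1 (18), Npr3, Ak4 and Pdha1 (17), and Tnnc1 and Hspb1 (16). Adapter trimming with cutadapt, alignment with HISAT2, read quality control with FastQC 0.11.9 and a test with DESeq2 are named in the submitters' processing notes. The table held 55487 genes and no entry that names no gene; 55141 identifiers were given symbols, biotypes and positions from GENCODE M21 (GRCm38), and 346 were left with their Ensembl identifier. A symbol carried by more than 1 identifier (106 symbols) was kept apart by identifier. All 32 value columns were used.

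Counts were rounded to whole numbers. The total per library ran from 16535498 to 54456977 counts. Genes were kept by edgeR's filterByExpr over the groups of a fit, which left 17536 genes in gastrocnemius, 18143 in soleus and 18726 in the fit of both muscles. Libraries were scaled by TMM factors. The test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3; estimateDisp, robust glmQLFit, glmQLFTest, 2-sided) with Benjamini-Hochberg adjustment and a threshold of 0.05. The 16 libraries of a muscle entered 1 fit with a mean per genotype, which gave each knockout against control, the double knockout against each single knockout, and the departure from additivity (double minus Acvr1b minus Tgfbr1 plus control). A fit of all 32 libraries gave the control soleus against the control gastrocnemius and the difference of each knockout effect between muscles. Residual degrees of freedom were 12 in each muscle, and the common biological coefficient of variation was 0.150 in gastrocnemius and 0.218 in soleus. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Levels are CPM of the TMM-scaled library size, as mean and SD over 4 libraries.

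Before the data were examined, 45 gene lists were fixed, 33 of pathways and 12 of markers of other cell types that a whole muscle holds. They were tested with camera (limma 3.58.1) with a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the lists of 1 comparison; 44 lists had enough measured members. A list score of a library is the mean over members of log2 CPM (prior count 2) minus the control mean of that muscle. The named genes were chosen by a rule fixed at the same time. Acvr1b, Tgfbr1, Myh7, Myh2, Myh1, Myh4, Mstn and Inhba are reported in every group. For double knockout against control, up to 10 rising and 10 falling genes were taken by size of the log2 fold change among those past the threshold, with at least 5 CPM in the higher group and no overlap between the libraries of the groups. The same rule took up to 6 and 6 for a single knockout against control, 4 and 4 for double against single knockouts and 10 and 10 for the control muscles, and without the condition on overlap 5 and 5 for additivity and for each difference between muscles. Genes without a symbol, predicted or clone-named genes, immunoglobulin and T-cell receptor segments and sex-linked genes were left out of this choice. Of each list, up to 4 members past the threshold with the largest log2 fold change could be named, or 2 with the highest level where none passed.

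The alternatives fixed in advance were DESeq2 1.42.0, size factors by the relative log expression method (RLE) in place of TMM, no filter on low counts, the replicate number or the mouse as a block, a fit of the compared groups alone, a fit of all 32 libraries for additivity, and each library left out in turn. Added after the data were seen were fits without 5 libraries in doubt and without 3 soleus libraries rich in nerve markers. Also added then were fits without genes within 20 Mb of Acvr1b or Tgfbr1 or on scaffolds outside the assembled chromosomes. The libraries in doubt were gastrocnemius control 1, Tgfbr1 KO 1 and double KO 1 and soleus Acvr1b KO 1 and double KO 1; the nerve-rich ones were soleus Acvr1b KO 3, Tgfbr1 KO 4 and double KO 2. Within the 24 pairs of replicates of 1 group in each muscle the chi-square per gene was at least 6.47, so no library was counted as a repeat of another. The same mouse gave both muscles: over 16 mice, the deviations of a mouse's libraries from their group means had a median correlation across genes of 0.208, against −0.00992 between muscles of different mice.

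The test was tried on simulated counts with 200 changed genes, drawn from the means and depths of the real libraries. For double knockout against control, it recovered 47.8% of 1.5-fold and 88.1% of 2-fold changes in gastrocnemius (17367 genes) and 26.9% and 73.1% in soleus (17971 genes). DESeq2 recovered 65.7% and 46.3% of the 1.5-fold changes in gastrocnemius and soleus. It made 26 and 29 false calls there, against 4 and 9 by edgeR. For additivity edgeR recovered 65.7% of 2-fold changes in gastrocnemius and 41.8% in soleus, and for the difference of the double-knockout effect between muscles 49.3% (18586 genes). Results for 3 genes are not reported here.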

Results

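Gastrocnemius medialis and soleus of control mice and of mice with myofibre-specific loss of Acvr1b, of Tgfbr1 or of both genes were compared by polyA RNA sequencing. Acvr1b (ALK4) and Tgfbr1 (ALK5) encode type I receptors through which activins, myostatin and TGF-β signal to SMAD2 and SMAD3. Each of the 8 groups held 4 libraries, the gastrocnemius and soleus libraries came from the same 16 mice, and total counts per library ran from 16535498 in gastrocnemius Tgfbr1 KO 1 to 54456977 in gastrocnemius Tgfbr1 KO 2. Libraries are named by genotype and replicate number.

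Acvr1b mRNA was low wherever the gene had been targeted. In gastrocnemius, Acvr1b (ENSMUSG00000000532, GRCm38 chromosome 15, 101174067 to 101213684, protein coding) measured 97.6 ± 8.05 CPM in controls (mean ± SD, n = 4), 23.6 ± 1.69 in Acvr1b KO, 78 ± 14.3 in Tgfbr1 KO and 16.2 ± 4.03 in double KO. Its log2 change against control was −2.05 (SE 0.150) in Acvr1b KO (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 2.86e-06) and −2.59 (SE 0.154) in double KO (adjusted p = 1.49e-08). In soleus it fell from 43.9 ± 8.23 CPM to 13.6 ± 1.48 in Acvr1b KO and 9.39 ± 1.86 in double KO (edgeR adjusted p = 0.000517 and 1.52e-05). The Tgfbr1 KO soleus libraries measured 29.6 ± 4.95 (log2 change −0.57, SE 0.163, edgeR adjusted p = 0.9999). In Tgfbr1 KO gastrocnemius the log2 change of Acvr1b was −0.33 (SE 0.144, edgeR adjusted p = 0.783). Neither passed the threshold.

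No fall of Tgfbr1 mRNA passed the threshold in the groups in which the gene had been targeted. Tgfbr1 (ENSMUSG00000007613, chromosome 4, 47353222 to 47414931, protein coding) measured 26.2 ± 6.56 CPM in control gastrocnemius and 27.1 ± 3.26 in the libraries labelled Tgfbr1 KO (log2 change 0.05, edgeR adjusted p = 0.999). It was higher in the libraries labelled double KO (44.3 ± 7.32 CPM, log2 change 0.76, SE 0.160, adjusted p = 0.00285). In soleus the means were 17.1 ± 1.77 in control, 15.7 ± 3.30 in Tgfbr1 KO (log2 change −0.12, adjusted p = 1.00) and 27.5 ± 20.1 in double KO, where double KO 1 alone measured 57.6 CPM. Counts over all exons of a gene do not show whether single exons were removed, so these values neither check nor contradict the Tgfbr1 labels, and directions drawn from these groups rest on the labels.

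**Figure D1:**
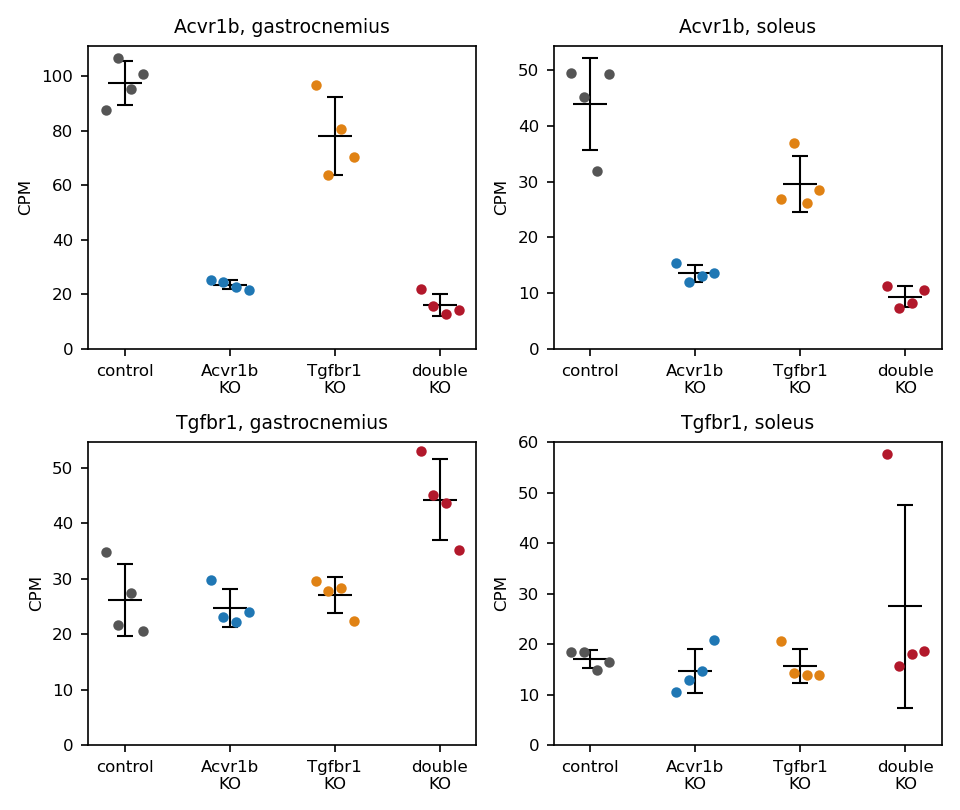
Acvr1b and Tgfbr1 levels in CPM (vertical axis, from 0) in each genotype and muscle; each point is 1 library and bars show the mean ± SD of 4. Acvr1b lies at 16.2 to 23.6 CPM on average in the gastrocnemius groups in which it was targeted, against 97.6 in controls, while the Tgfbr1 KO libraries overlap the controls for Tgfbr1 in both muscles.

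In the fast gastrocnemius, Acvr1b KO was first compared with control. Few genes were called, and all of them lay on chromosome 15 near Acvr1b. Slc4a8 (100761747 to 100823968), a sodium-driven bicarbonate transporter gene, fell from 8.56 to 2.54 CPM (log2 change −1.75, SE 0.193, edgeR adjusted p = 0.000633). The zinc finger gene Zfp641 (98285585 to 98296161) rose from 16.6 to 27.3 CPM (0.72, SE 0.115, adjusted p = 0.0401). With Acvr1b, and with Mettl7a3 (2.06) and Gm49492 (−2.17), which were named after their values were seen and had fractional counts in 32 and 19 of the 32 libraries, 5 genes were called among 17536 tested, of which 2 rose and 3 fell, and 775 had an unadjusted p under 0.05. DESeq2 called 26. The Zfp641 call was lost without any of Acvr1b KO 2, 3 and 4 or control 2, 3 and 4 (adjusted p 0.0511 to 0.234), with only the compared groups in the fit (0.107) and with the replicate as a block (0.0827). The count was 3 without each of these 6 libraries and 9 without Acvr1b KO 1.

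Of the fixed lists in the same comparison, 9 passed camera with the preset correlation and 0 passed with an estimated correlation. The immediate early genes, transcription factors and regulators that respond rapidly to stimulation, had a median log2 change of −0.24 (adjusted p = 5.71e-05, and adjusted p = 0.757 with an estimated correlation). Of their 24 members 0 were past the threshold over all genes or adjusted over the list alone. The mitochondrially encoded mRNAs had a median of −0.62 (adjusted p = 0.000547, and adjusted p = 0.988 with an estimated correlation). Their call was lost without control 1 (adjusted p = 0.465), the control library with 25.99% of its counts on mitochondrial genes against 10.4 to 13.9% in the other controls.

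The genes called in gastrocnemius between Tgfbr1 KO and control lay mainly near Tgfbr1 or on scaffolds outside the assembled chromosomes. Of 30 genes called, 20 lay within 20 Mb of Tgfbr1 on chromosome 4 and 6 on scaffolds. Most of the 20 were members of a repeated block between 41.9 and 42.9 Mb that holds copies of the chemokine gene Ccl21b. The genes with a name by the rule were Cox11, a copper chaperone gene for cytochrome c oxidase (14.5 against 10.5 CPM, log2 change 0.47, SE 0.083, edgeR adjusted p = 0.0237), Klf15 and Mapk1ip1. Klf15, a glucocorticoid-responsive transcription factor gene, fell (42.6 against 67.7 CPM, −0.67, SE 0.129, adjusted p = 0.0433), as did Mapk1ip1 (26.1 against 37.5 CPM, −0.52, SE 0.095, adjusted p = 0.0273). In all, 3 genes rose and 27 fell, 1052 had an unadjusted p under 0.05, and DESeq2 called 57. The Klf15 and Mapk1ip1 calls were lost without any of control 2, 3 and 4 or Tgfbr1 KO 2, 3 and 4 (adjusted p up to 0.230 and 0.177), and the Cox11 call without any library but control 1 (up to 0.0874). With only the compared groups in the fit all 3 were lost (0.142 to 0.226), as they were with the replicate as a block (0.0507 to 0.0604). Without the 3 gastrocnemius libraries in doubt, a set chosen after the data were seen, 100 genes were called, with Cox11 not among them (0.0547). Without the genes near both targeted genes and on scaffolds 0 were called (989 at an unadjusted p under 0.05).

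The list tests of Tgfbr1 KO against control in gastrocnemius gave 4 calls with the preset correlation and 0 with an estimated one. Cytosolic ribosomal protein genes had a median log2 change of −0.11 (camera adjusted p = 1.04e-09, and adjusted p = 0.910 with an estimated correlation) and immediate early genes −0.31 (7.34e-05, and adjusted p = 0.530 with an estimated correlation). Neutrophil markers had a median of −0.61 (1.06e-05, and adjusted p = 0.530) and adipocyte markers −0.65 (0.000179, and adjusted p = 0.564). Tgfbr1 KO 1 scored −1.91 for neutrophil markers, against −0.58 to −0.37 in the other Tgfbr1 KO libraries. For adipocyte markers it scored −1.31, against −0.92 to −0.16. Over all genes tested 0 members of these 4 lists passed; adjusted over the list alone, 1 immediate early gene rose and 2 fell, and 2 of 7 neutrophil markers fell.

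**Figure D2:**
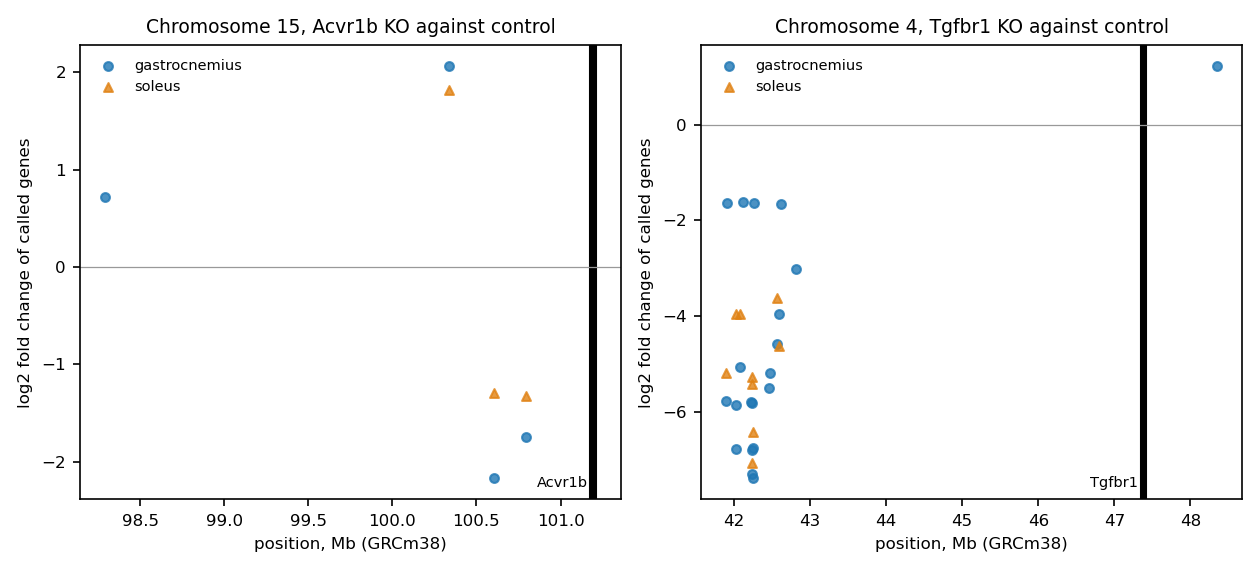
Genes called in the single knockouts on chromosome 15 (Acvr1b KO) and chromosome 4 (Tgfbr1 KO), by position in Mb (horizontal axis) and log2 fold change against control (vertical axis); circles are gastrocnemius, triangles soleus, and the black bar marks the targeted gene. All 4 further genes of gastrocnemius Acvr1b KO and 20 of the 30 of gastrocnemius Tgfbr1 KO lie within 20 Mb of the targeted gene.

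Many genes differed between double KO and control gastrocnemius. Sarcolipin (Sln), an inhibitor of the calcium pump of the sarcoplasmic reticulum, rose from 0.951 to 19.8 ± 8.33 CPM (log2 change 4.36, SE 0.379, edgeR adjusted p = 9.32e-07). Cardiac α-actin (Actc1) rose from 134 to 1173 CPM (3.13, SE 0.363, adjusted p = 1.58e-05). Shisal1 (4.12, SE 0.218), the antisense RNA Srrm4os (4.06, SE 0.244), the microtubule-severing protein gene Katnal2 (3.46, SE 0.213) and the calcium-activated potassium channel gene Kcnn3 (3.27, SE 0.350) rose as well, with adjusted p from 3.56e-09 to 7.50e-06. Fam174b (3.47), Gstt3 (3.05), Kif5c (2.97) and Cyp4f39 (2.91) completed the 10 genes with the largest rise by the rule. Lipocalin 2 (Lcn2; −3.42, SE 0.647, adjusted p = 0.0013), the zinc transporter gene Slc30a2 (−2.62, SE 0.224, adjusted p = 8.43e-07), the stress sensor gene Gadd45b (3.72 against 22.02 CPM, −2.55, SE 0.387, adjusted p = 0.00021) and Gadl1, a decarboxylase gene of the carnosine pathway (−2.51, SE 0.119, adjusted p = 1.48e-09), were among those that fell most. So were Acvr1b itself, Odf3l2 (−2.71), Cdhr3 (−2.39) and Slc4a8 (−2.33). The nuclear receptor gene Nr4a3, which lies next to Tgfbr1 (chromosome 4, 48045153 to 48086447), fell from 63.7 to 7.42 CPM (−3.12, SE 0.614, adjusted p = 0.00175; −3.71 without double KO 1 and −2.42 without control 1). Sox4 measured 8.44 against 113 CPM (−3.76, SE 1.18, adjusted p = 0.0346), a call that was lost without double KO 2, 3 or 4 or control 2 or 4 (adjusted p 0.0568 to 0.0925) and without the filter on low counts (0.0984), with a value of −4.66 without double KO 1. Actc1 and Gadl1 had fractional counts in 24 and 26 of the 32 libraries.

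In numbers, 3673 of 17536 genes differed between double KO and control gastrocnemius, 1991 higher and 1682 lower, and 564 rose and 354 fell by more than 1 on the log2 scale. With only these 8 libraries in the fit the count was 2330. The 4 double-KO animals carry numbers apart from those of all other mice, so cohort and genotype cannot be told apart.

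Genes of the denervation and neuromuscular junction list rose together in the double-KO gastrocnemius. Of 22 measured members, 16 rose and 0 fell (16 rose and 2 fell when adjusted over the list alone), with a median log2 change of 1.02 (camera adjusted p = 9.64e-10). This was the only one of 19 list calls that held with an estimated correlation (adjusted p = 0.0174). Chrne, the ε subunit of the adult acetylcholine receptor, rose from 8.31 ± 1.44 to 50.1 ± 2.46 CPM (2.59, SE 0.111, edgeR adjusted p = 5.38e-10). The growth arrest gene Gadd45a rose from 20.1 to 128 ± 120 CPM (2.68, SE 0.414, adjusted p = 0.000247; 1.77 without double KO 1). Myogenin (Myog; 1.80) also passed, but not without double KO 1 (0.62, adjusted p = 0.0815), without the libraries in doubt (0.48, 0.0924), without the filter on low counts (0.0789), with the replicate as a block (0.0541) or with only the compared groups in the fit (0.0893). The list score was 1.25 in double KO 1 and 0.58 to 0.68 in double KO 2, 3 and 4, against −0.06 to 0.09 in the controls. The score of the 12 Schwann cell and nerve markers was −0.75 to −0.32 in the 4 double-KO libraries and −0.24 to 0.22 in the controls. It was −0.35 to −0.30 in Tgfbr1 KO 2, 3 and 4, 0.24 in Tgfbr1 KO 1 and −0.08 to 1.12 in Acvr1b KO. Of these markers 0 were called between double KO and control (median −0.55, camera adjusted p = 0.0644).

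Slow-fibre contractile genes fell in the double-KO gastrocnemius. Of 18 members, 2 rose and 11 fell (2 and 12 when adjusted over the list alone; median −0.79, camera adjusted p = 8.57e-07, and adjusted p = 0.379 with an estimated correlation). Slow troponin T (Tnnt1) went from 232 to 108 CPM (−1.11, SE 0.148, edgeR adjusted p = 5.97e-05), myoglobin (Mb) from 2074 to 988 CPM (−1.07, SE 0.150, adjusted p = 9.25e-05). Tnnc1 and Tnni1 fell by 1.05 and 1.04 on the log2 scale (adjusted p = 0.000131 and 0.000451). Among the myosin heavy chains, Myh7 (type I fibres) fell from 749 to 391 CPM (−0.94, SE 0.149, adjusted p = 0.00031), Myh2 (IIA) by 0.58 (SE 0.108, adjusted p = 0.00115) and Myh4 (IIB) by 0.47 (SE 0.100, adjusted p = 0.00339). Myh1 (IIX) measured −0.39 (adjusted p = 0.0748). These 4 genes had fractional counts in 31 or 32 libraries, as did Tnnt3. Of 18 fast-fibre genes, 2 rose and 6 fell (2 and 9 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.105). Mybph, a myosin-binding protein gene, rose from 50.4 to 361 CPM (2.84, SE 0.381), and fast troponin T (Tnnt3) fell by 0.48. The slow-fibre score was −1.06 in double KO 1 and −0.22 to −0.52 in the other double-KO libraries.

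Most called genes of the oxidative metabolism lists were lower in the double-KO gastrocnemius. Of 79 nuclear-encoded respiratory chain genes, 0 rose and 33 fell (39 fell when adjusted over the list alone; median −0.25, camera adjusted p = 9.64e-10, and adjusted p = 0.6003 with an estimated correlation). Examples were the complex I gene Ndufa5 (120 to 85.6 CPM, −0.48, SE 0.087, edgeR adjusted p = 0.000888), the complex III gene Uqcrh (−0.46) and the ATP synthase gene Atp5o (−0.46). In the TCA cycle list 8 of 30 genes fell and 0 rose (12 fell adjusted over the list alone; camera adjusted p = 0.000818, and adjusted p = 0.6003 with an estimated correlation), with Idh3g at −0.45 and Pdha1 at −0.40. In the fatty acid list 11 of 34 fell and 0 rose (13 fell adjusted over the list alone; camera adjusted p = 0.000589, and adjusted p = 0.607 with an estimated correlation). Among them were Plin5 (−1.19), Ucp3 (−0.90) and the lipoprotein lipase gene Lpl (−0.74, adjusted p = 9.15e-05). Of 29 mitochondrial biogenesis regulators 2 rose and 9 fell (2 and 12 adjusted over the list alone; camera adjusted p = 0.00681, and adjusted p = 0.379 with an estimated correlation). Ppargc1a (PGC-1α), a coactivator of oxidative genes, fell from 52.5 to 25.01 CPM (−1.07, SE 0.183, adjusted p = 0.000575) and Ppara by 1.29 (SE 0.242, adjusted p = 0.00121). Of 36 glycolysis and glycogen genes, 2 rose and 10 fell (3 and 13 adjusted over the list alone; camera adjusted p = 0.0231, and adjusted p = 0.607 with an estimated correlation; lost without double KO 1 or control 4, 0.153 at most). The gluconeogenic gene Fbp2 fell by 1.67 (SE 0.140, adjusted p = 7.13e-07), while hexokinase 1 (Hk1) rose from 7.43 to 18.5 CPM (1.31, SE 0.088).

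Target genes of BMP signalling, the other branch of the TGF-β family, rose. Of 12, 7 rose and 0 fell, over all genes and adjusted over the list alone (median 0.56, camera adjusted p = 0.00681, and adjusted p = 0.133 with an estimated correlation). Smad9 rose from 0.134 to 1.14 CPM (2.98, SE 0.432, edgeR adjusted p = 0.000133), Id3 by 1.44 (SE 0.257) and Id1 by 1.09 (SE 0.273), and Id2 by 1.42 (0.83 without double KO 1). The Id2 call was lost without the libraries in doubt (0.76, adjusted p = 0.0747) and with only the compared groups in the fit (0.0572). Of 18 targets of TGF-β and activin, 5 rose and 3 fell (5 and 7 adjusted over the list alone; camera adjusted p = 0.666). Pmepa1, a feedback inhibitor, fell from 20.8 to 9.24 CPM (−1.17, SE 0.133, adjusted p = 1.32e-05), and Ltbp2 (1.53, SE 0.268) and Tgfbi (0.83, SE 0.119) rose. Among ligands and antagonists 8 of 29 rose and 3 fell (9 and 3 adjusted over the list alone; camera adjusted p = 0.0419, and adjusted p = 0.6003 with an estimated correlation; lost without double KO 2 or 4 or control 1 or 4, 0.0950 at most). The myostatin relative Gdf11 rose from 16.9 to 43.9 CPM (1.38, SE 0.124, adjusted p = 1.29e-06) and activin A (Inhba) from 1.40 to 3.98 CPM (1.51, SE 0.335, adjusted p = 0.00417). Myostatin (Mstn) itself measured −0.24 (adjusted p = 0.313). Of 10 other family receptors, 1 rose (Tgfbr2, 0.36).

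Growth and protein turnover genes went both ways. Of 32 genes of IGF, Akt and mTOR signalling, 4 rose and 8 fell (4 and 10 adjusted over the list alone; camera adjusted p = 0.234). The IGF-binding protein gene Igfbp5 rose from 660 to 1824 CPM (1.47, SE 0.200, edgeR adjusted p = 7.44e-05). Foxo1, a transcription factor of muscle wasting, fell from 174 to 72.7 CPM (−1.26, SE 0.223, adjusted p = 0.000741), as did Sesn1 (−1.18, SE 0.256). Of 17 atrophy-related ubiquitin ligases, 1 rose and 3 fell, the same adjusted over the list alone, among them Trim54 (−0.36) and Cblb (−0.53). Of 75 cytosolic ribosomal protein genes 12 fell and 0 rose (10 fell adjusted over the list alone; camera adjusted p = 0.000162, and adjusted p = 0.607 with an estimated correlation), for example Rps12 by 0.36. Of 41 ribosome biogenesis genes 9 rose and 0 fell (10 rose adjusted over the list alone; camera adjusted p = 0.0113, and adjusted p = 0.607 with an estimated correlation; lost without double KO 1 or control 3, 0.229 at most), for example Rrp12 (0.53) and Utp20 (0.56). The small heat shock protein genes Hspb8 (333 to 1016 CPM, 1.61, SE 0.111, adjusted p = 7.84e-08) and Hspb1 (1.09) and the muscle regulatory factors Myod1 (1.27 to 6.02 CPM, 2.26, SE 0.272, adjusted p = 2.28e-05) and Myf6 (1.24) rose. Of 24 immediate early genes 1 rose and 5 fell (1 and 7 adjusted over the list alone; camera adjusted p = 0.0231, and adjusted p = 0.6003 with an estimated correlation; 0.102 without control 3), with Zfp36 at −1.35 and Nr4a1 at −1.23.

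Markers of other cell types differed between double KO and control, not all in 1 direction. Macrophage markers rose (7 of 14, 0 fell; 8 and 1 adjusted over the list alone; camera adjusted p = 0.00289, and adjusted p = 0.6003 with an estimated correlation), including Trem2 (3.74, edgeR adjusted p = 0.000882; 3.05 without double KO 1), Adgre1 (1.18) and Lyz2 (1.15). Interferon response genes rose (8 of 20, 0 fell; 9 adjusted over the list alone; camera adjusted p = 0.00289, and adjusted p = 0.379 with an estimated correlation), with Ifit1 at 1.21 and Irf1 at 1.16. Fibroblast markers rose (5 of 15, 0 fell, the same adjusted over the list alone; camera adjusted p = 0.00894, and adjusted p = 0.6003 with an estimated correlation), with Lum at 1.05 and Pdgfra at 0.78. Endothelial markers fell (6 of 15, 0 rose; camera adjusted p = 0.00894, and adjusted p = 0.379 with an estimated correlation), with Emcn at −0.81 and Flt1 at −0.45. Smooth muscle markers fell as well (6 of 12 fell, 1 rose; camera adjusted p = 0.0231, and adjusted p = 0.6003 with an estimated correlation; 0.0643 without control 1), with Myh11 at −0.70. Among tendon markers, which also fell (4 of 12 fell, 0 rose; camera adjusted p = 0.00607, and adjusted p = 0.6003 with an estimated correlation), Kera changed by −1.19. The counts for these 3 lists were equal when adjusted over the list alone. The macrophage score was 1.25 in double KO 1 and 0.37 to 0.53 in double KO 2, 3 and 4.

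**Figure D3:**
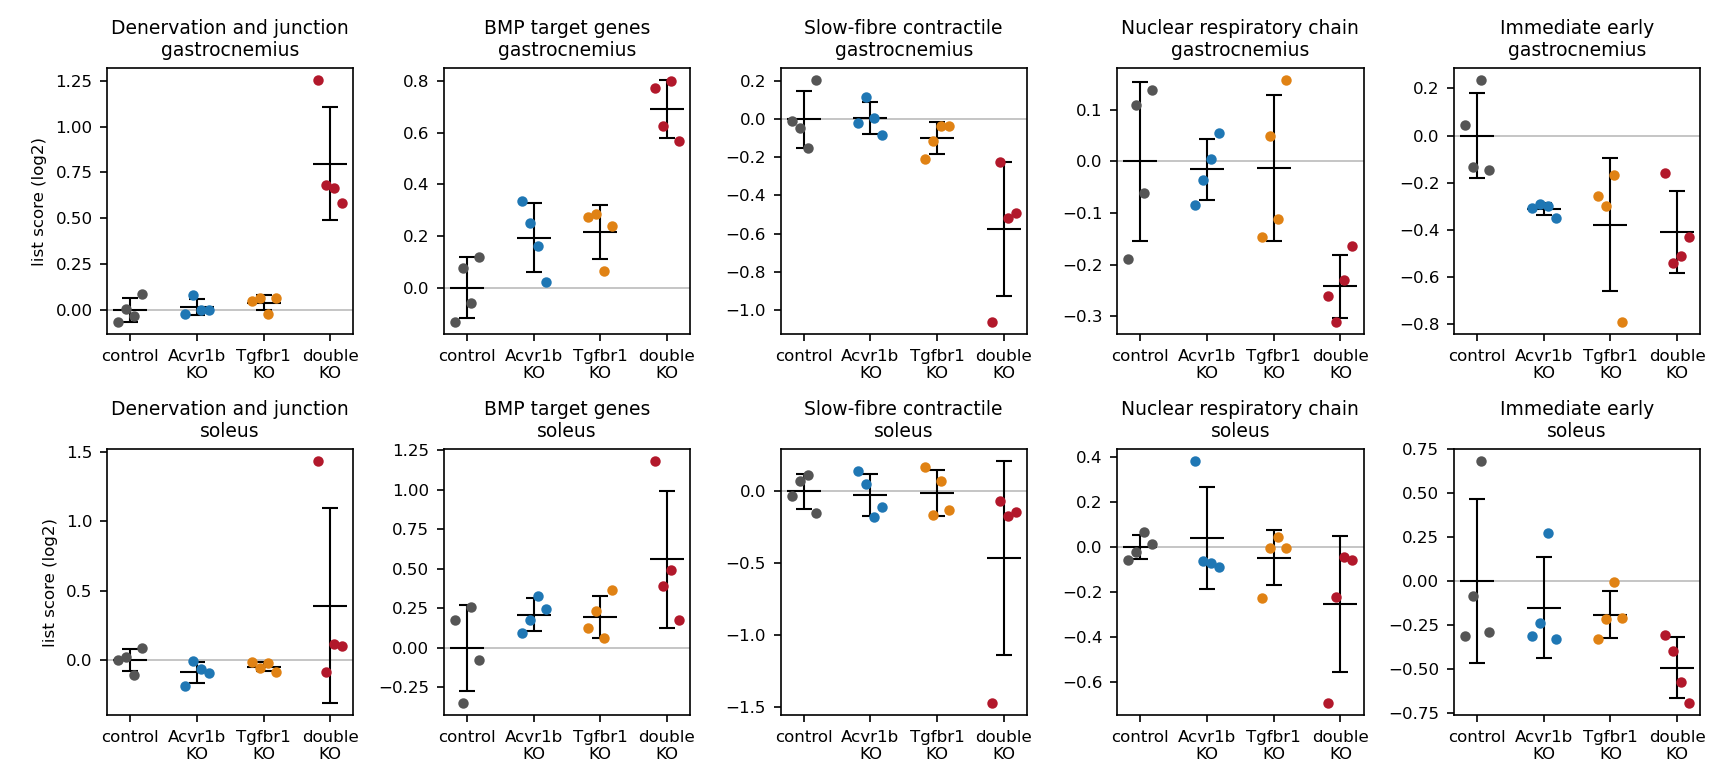
Scores of 5 gene lists per library (vertical axis, mean log2 CPM of the members minus the control mean of that muscle) by genotype in gastrocnemius and soleus; each point is 1 library and bars show the mean ± SD of 4. In gastrocnemius the denervation and neuromuscular junction score of the double KO lies between 0.58 and 1.25, above all other groups, and in soleus double KO 1 stands apart at 1.44.

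The double knockout was then set against each single knockout in gastrocnemius, where cohort and genotype again cannot be told apart. Against Acvr1b KO, Sln (4.55, SE 0.387), Shisal1 (4.35), Srrm4os (3.87) and Fam174b (3.67) were higher. Odf3l2 (−2.76), Slc30a2 (−2.50) and Nr4a3 (−2.39, edgeR adjusted p = 0.0118; −2.98 without double KO 1; lost without the filter on low counts, 0.0592) were lower, as was haptoglobin (Hp; −2.68, adjusted p = 0.00361; −1.73 without Acvr1b KO 1). Against Tgfbr1 KO, Sln (4.29, SE 0.383, adjusted p = 2.28e-06), Srrm4os (3.72), Katnal2 (3.69) and Shisal1 (3.69) were higher, and Cdhr3 (−2.35), Acvr1b (−2.27), Gadl1 (−2.25) and Slc30a2 (−2.09) were lower. The denervation and neuromuscular junction list rose in both comparisons. It rose by 14 of 22 members with 0 lower against Acvr1b KO (16 and 1 adjusted over the list alone; camera adjusted p = 0.0102 with an estimated correlation). It rose by 13 members with 1 lower against Tgfbr1 KO (16 and 1 adjusted over the list alone; adjusted p = 0.0070 with an estimated correlation). Endothelial markers fell against Tgfbr1 KO (6 of 15, and 7 adjusted over the list alone; median −0.35, adjusted p = 0.0358 with an estimated correlation). Of 79 respiratory chain genes 19 were lower than in Acvr1b KO and 20 lower than in Tgfbr1 KO, with 0 higher (28 lower, and 38 lower with 1 higher, adjusted over the list alone). These calls held with the preset correlation (3.23e-09 and 3.17e-12) and not with an estimated one (adjusted p = 0.585 and 0.456). In numbers, 2852 genes differed from Acvr1b KO (1614 higher, 1238 lower) and 2255 from Tgfbr1 KO (1304 higher, 951 lower). Without the libraries in doubt, 4322 differed from Acvr1b KO.

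The departure from additivity compared the double knockout with the sum of the single-knockout effects. The double-KO mice carry numbers apart from all others, so an effect of their cohort would enter this departure in full. In gastrocnemius the change of Sln exceeded the sum by 4.48 (SE 0.579, edgeR adjusted p = 0.000468), that of Shisal1 by 3.92 (SE 0.355, adjusted p = 1.23e-05) and that of Srrm4os by 3.53 (SE 0.347, adjusted p = 3.13e-05). Slc30a2 (−1.96, SE 0.301), the glucose transporter gene Slc2a3 (−1.93, SE 0.212, adjusted p = 8.00e-05), Gadl1 (−1.79, SE 0.160) and the amino acid transporter gene Slc38a2 (−1.74, SE 0.283, adjusted p = 0.00338) lay below the sum, and Slc2a3 had fractional counts in 29 of the 32 libraries. Slc38a2 measured 358.2 ± 115.8 CPM in Acvr1b KO, against 172.5 in control, 185.2 in Tgfbr1 KO and 115.5 in double KO. It lies within 20 Mb of Acvr1b (chromosome 15, 96687392 to 96699730). The denervation and neuromuscular junction list lay above it (4 of 22 members past the threshold and 0 below; 12 and 1 adjusted over the list alone; median 0.81, camera adjusted p = 0.0079 with an estimated correlation). Endothelial markers lay below it (2 of 15, and 6 adjusted over the list alone; median −0.32, adjusted p = 0.0299 with an estimated correlation). Of the 79 respiratory chain genes 0 passed singly, with a median of −0.24 (camera adjusted p = 2.84e-09, and adjusted p = 0.511 with an estimated correlation). In all, 376 genes departed from additivity, 259 above and 117 below, with 734 by DESeq2, 146 with all 32 libraries in 1 fit and 792 without the libraries in doubt. Without Acvr1b KO 1, 2 or 3, double KO 3, control 3 or Tgfbr1 KO 2 the count was 232 to 249. The calls of Ankrd1 (3.21, adjusted p = 0.0409), Fam174b (3.20, 0.0287) and Odf3l2 (−1.98, 0.0266) were the other 3 by the rule. Fam174b was lost without Acvr1b KO 1, 2 or 3, control 2 or 3 or Tgfbr1 KO 3 or 4 (0.0509 to 0.0647), and Odf3l2 without Acvr1b KO 1 or 3, double KO 2 or 3, control 3 or Tgfbr1 KO 1 or 3 (0.0512 to 0.0631). Ankrd1 was lost without any Acvr1b KO or Tgfbr1 KO library or control 1, 3 or 4 (0.0511 to 0.0894), while its value without double KO 1 was 2.03. With all 32 libraries in 1 fit Ankrd1 (0.413) and Odf3l2 (0.334) were lost, and without the filter on low counts all 3 were (Ankrd1 0.167, Fam174b 0.122, Odf3l2 0.114). Ankrd1 was also lost with the replicate as a block (0.104).

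In soleus, few genes were called in each single knockout. In Acvr1b KO, Acvr1b and Slc4a8 (3.72 against 9.33 CPM, −1.33, SE 0.165, edgeR adjusted p = 0.0054) fell. With Mettl7a3 (1.82) and Gm49492 (−1.30) 4 genes were called among 18143, all near Acvr1b on chromosome 15 (353 at an unadjusted p under 0.05, 9 by DESeq2, 23 without the libraries in doubt, 1 without the nerve-rich libraries, where Slc4a8 was lost at 0.0725). In Tgfbr1 KO, 9 genes fell and 0 rose, all within 20 Mb of Tgfbr1 and none with a name by the rule (410 at an unadjusted p under 0.05, 19 by DESeq2, 17 without the filter on low counts, 34 without the libraries in doubt, 4 without the nerve-rich libraries). Leaving out control 1, control 4 or Tgfbr1 KO 2, 3 or 4 gave 4 or 5 calls, and leaving out control 3 gave 15. With the preset correlation 9 lists passed in each comparison and 0 passed with an estimated one. The immediate early genes had a median of −0.16 in Acvr1b KO (camera adjusted p = 0.00219, and adjusted p = 0.896 with an estimated correlation) and of −0.22 in Tgfbr1 KO (6.03e-05, and adjusted p = 0.961). Neutrophil markers had a median of −0.65 in Tgfbr1 KO (1.56e-06, and adjusted p = 0.961). Their score was −1.41 in Tgfbr1 KO 1 and −0.50 to −0.21 in the other Tgfbr1 KO libraries. Adjusted over the list alone, 2 immediate early genes fell in Tgfbr1 KO, against 0 members of either list over all genes. The call of the immediate early genes was lost without Acvr1b KO 4 or control 3 in Acvr1b KO (0.745 at most) and without control 3 in Tgfbr1 KO (0.442). The nerve marker score was 2.27 in Acvr1b KO 3 and 2.21 in Tgfbr1 KO 4.

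Fewer genes differed between double KO and control in soleus. Sln rose from 24.8 to 56.3 CPM (1.18, SE 0.178, edgeR adjusted p = 0.00535), Ddit4l, an inhibitor gene of mTOR signalling, from 24.99 to 57.2 CPM (1.20, SE 0.200, adjusted p = 0.0101). Mettl7a2, which lies near Acvr1b, rose from 2.10 to 5.93 CPM (1.501, SE 0.253, adjusted p = 0.0107). Mettl7a2 and Ddit4l had fractional counts in 24 and 19 of the 32 libraries. Lcn2 fell from 17.7 to 1.43 CPM (−3.62, SE 0.597, adjusted p = 0.0091), Gadd45b from 41.3 to 7.22 CPM (−2.52, SE 0.354, adjusted p = 0.00453). The glucocorticoid-induced gene Fkbp5 fell from 202 to 78.8 CPM (−1.36, SE 0.200, adjusted p = 0.00503) and Tinagl1 from 47.5 to 16.96 CPM (−1.49, SE 0.226, adjusted p = 0.00535). Doc2b (−1.81, SE 0.315) and Slc4a8 (−1.53, SE 0.167) fell as well, and so did Foxo1 (125 to 62.5 CPM, −1.002, SE 0.164, adjusted p = 0.00896), Sesn1 (−1.07, SE 0.184), Zfp36 (−1.34, SE 0.201) and Nfil3 (−1.18, SE 0.185). With only the compared groups in the fit the calls of Ddit4l (0.130), Mettl7a2 (0.117), Gadd45b (0.0689), Zfp36 (0.0672) and Foxo1 (0.0595) were lost, and without the nerve-rich libraries those of Lcn2 (0.0584), Doc2b (0.0631) and Foxo1 (0.0584). Of the myosin heavy chain genes, Mstn and Inhba, 0 passed: Myh7 measured −0.24 (adjusted p = 0.624) and Myh4 1.26 (SE 0.663, adjusted p = 0.473).

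Other calls in double-KO soleus by the rule were lost without single libraries. Pak1 (0.97) was lost without control 3 or 4 (edgeR adjusted p 0.0524 and 0.0570), Sort1 (0.87) without control 2 or 4 (0.0573 and 0.0572), and Ypel2 (0.92) without control 2, 3 or 4 (0.0943 to 0.141). Fdxr (0.89) was lost without any control (0.0514 to 0.0778), Prkab2 (0.90) without double KO 4 or control 1, 3 or 4 (0.0531 to 0.0833). Cxxc5 (1.21) was lost without double KO 3 or control 2, 3 or 4 (0.0563 to 0.0735), and Prex1 (1.11) without double KO 2 or any control (0.0619 to 0.155). Among the falling genes, the glycogen-targeting subunit gene Ppp1r3c (1238 to 428 CPM, −1.53) was lost without double KO 2 or control 2 or 4 (0.0571 to 0.0815). Gprc5a (−1.54) was lost without double KO 3 or 4 or control 2 or 3 (0.0582 to 0.0837), and Sphk1 (−1.72, with fractional counts in 22 libraries) without any of the 8 libraries (0.0643 to 0.137). With only the compared groups in the fit all of these but Sphk1 were lost (0.0538 to 0.238). Without the nerve-rich libraries Ypel2 (0.0545), Cxxc5 (0.0615), Ppp1r3c, Prex1 and Sphk1 (up to 0.130) were lost. With the replicate as a block Pak1, Prkab2, Prex1, Ppp1r3c, Gprc5a and Sphk1 were lost (0.0555 to 0.0986), as was Sphk1 without the filter on low counts (0.0693), and Prex1 (0.0591) and Sphk1 (0.0567) without the genes near both targeted genes. In all, 131 genes differed in soleus, 40 higher and 91 lower, with 2219 at an unadjusted p under 0.05. The count was 410 by DESeq2, 35 with only these 8 libraries in the fit, 308 without double KO 1, 69 without control 2 and 64 without control 4. Without the libraries in doubt it was 499, without the nerve-rich libraries 62 and without the genes near both targeted genes 80.

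Lists in double-KO soleus gave 11 calls with the preset correlation and 0 with an estimated one. Of 79 respiratory chain genes 0 passed singly, with a median of −0.23 (camera adjusted p = 1.26e-14, and adjusted p = 0.910 with an estimated correlation). Slow-fibre genes had a median of −0.38 (5.86e-07, and adjusted p = 0.910; 0 passed over all genes and 1 fell adjusted over the list alone). Immediate early genes had a median of −0.41 (2.97e-07, and adjusted p = 0.648; 1 fell over all genes and 6 adjusted over the list alone). BMP target genes had a median of 0.53 (0.00636, and adjusted p = 0.648; 1 rose over all genes and 4 adjusted over the list alone; 0.0631 without double KO 1). Ribosome biogenesis genes had a median of 0.51 (2.35e-06, and adjusted p = 0.910; 0.320 without double KO 1). The score of double KO 1 was −1.47 for slow-fibre genes and 1.38 for ribosome biogenesis, against −0.07 to −0.17 and −0.11 to 0.01 in the other double-KO libraries, and its respiratory chain score was −0.69 against −0.05 to −0.22.

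Against the single knockouts in soleus, Sln (1.07, SE 0.177, edgeR adjusted p = 0.0254), Pak1 (1.14), the adenylate kinase gene Ak4 (1.16, SE 0.151, adjusted p = 0.00487) and Trp53bp1 (0.59) were higher in double KO than in Acvr1b KO. Tinagl1 (−1.498, SE 0.226, adjusted p = 0.0143) and Fkbp5 (−1.12, SE 0.199, adjusted p = 0.0372) were lower. Against Tgfbr1 KO, the glycolytic regulator gene Pfkfb3 (1.76, SE 0.289, adjusted p = 0.0395) and Mettl7a2 (1.53, SE 0.252, adjusted p = 0.0395) were higher, and Acvr1b (−1.65) and Slc4a8 (−1.44, SE 0.167, adjusted p = 0.00143) lower. Pfkfb3, Mettl7a2 and Ak4 had fractional counts in 31, 24 and 17 of the 32 libraries. Tinagl1 was lost without double KO 3 (0.0558), Sln without Acvr1b KO 2, 3 or 4 or double KO 3 or 4 (0.0587 to 0.0799). Pak1 was lost without Acvr1b KO 1, 2 or 4 or double KO 3 or 4 (0.0587 to 0.108), Trp53bp1 without Acvr1b KO 1 or 3 or double KO 4 (0.0598 to 0.0854). Fkbp5 was lost without Acvr1b KO 1, 2 or 3 or double KO 2, 3 or 4 (0.0545 to 0.11), Mettl7a2 without any Tgfbr1 KO library (0.0678 to 0.199), and Pfkfb3 without any of these 8 libraries but double KO 2 (0.0612 to 0.201). With only the compared groups in the fit all named calls against Acvr1b KO were lost (0.189 to 0.578), as were Pfkfb3 (0.310), Mettl7a2 (0.369) and Slc4a8 (0.119) against Tgfbr1 KO. Without the nerve-rich libraries all but Ak4, Acvr1b and Slc4a8 were lost (0.0780 to 0.268). Without the genes near both targeted genes Sln, Pak1 and Trp53bp1 (0.0637 each), Fkbp5 (0.101) and Pfkfb3 (0.124) were lost. Pak1, Trp53bp1 and Fkbp5 were lost with the replicate as a block (0.0586 to 0.0850), Pak1 without the libraries in doubt (0.104) and Pfkfb3 without the filter on low counts (0.0638). The counts were 23 against Acvr1b KO (7 higher, 16 lower) and 9 against Tgfbr1 KO (6 higher, 3 lower), and 152 and 84 by DESeq2. Without Acvr1b KO 1 or 2 or double KO 2, 3 or 4 the first was 8 to 14, and without double KO 3 or Tgfbr1 KO 1, 3 or 4 the second was 4 or 5. Without the libraries in doubt they were 13 and 44, without the nerve-rich ones 7 and 4, with only the compared groups 0 and 2, and without the genes near both targeted genes 2 and 0. Of additivity in soleus 0 genes departed by edgeR and 0 by DESeq2, with 614 at an unadjusted p under 0.05 in edgeR.

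The control soleus and gastrocnemius differed by fibre type. All 18 slow-fibre genes were higher in soleus (median 3.29, camera adjusted p = 9.58e-42, and adjusted p = 0.00247 with an estimated correlation). Examples were the ventricular light chains Myl3 (2928 against 202 CPM, 3.86, SE 0.248, edgeR adjusted p = 5.14e-13) and Myl2 (3.81) and Tnnc1 (3.65). Sln was higher as well (22.8 against 1.04 CPM, 4.44, SE 0.330, adjusted p = 1.04e-11). Of the fast-fibre genes 16 were lower and 1 higher (median −1.78, adjusted p = 0.0286 with an estimated correlation), with Myh4 at −5.41 (−6.04 without soleus control 2) and α-actinin 3 (Actn3) at −5.03 (SE 0.553), which had fractional counts in 32 and 20 libraries. Mstn was lower in soleus (3.33 against 110 CPM, −5.04, SE 0.470, adjusted p = 9.68e-10). Of the fatty acid genes 31 were higher and 1 lower (median 1.00, camera adjusted p = 8.28e-15, and adjusted p = 0.194 with an estimated correlation). Of the respiratory chain genes 51 were higher and 0 lower (59 higher adjusted over the list alone; 6.94e-08, and adjusted p = 0.720). Of the glycolysis and glycogen genes 6 were higher and 21 lower (7 and 22 adjusted over the list alone; 1.13e-12, and adjusted p = 0.144). In all, 7573 of 18726 genes differed, 3837 higher and 3736 lower in soleus.

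Whether a knockout effect differed between the muscles was tested directly. For Acvr1b KO and for Tgfbr1 KO, 0 genes passed by edgeR and 0 by DESeq2 (244 and 257 at an unadjusted p under 0.05 in edgeR). The double-KO effect differed for 137 genes. The rise of Sln on the log2 scale was smaller in soleus (log2 difference −3.18, SE 0.414, edgeR adjusted p = 5.40e-05). In CPM it was not, since Sln went from 22.8 to 51.5 in soleus and from 1.04 to 21.45 in gastrocnemius. The control level was thus higher in soleus. Fam174b (−3.77, SE 0.612, adjusted p = 0.000924), Srrm4os (−3.06, SE 0.482, adjusted p = 0.000636), the natriuretic peptide receptor gene Npr3 (−2.63, SE 0.298, adjusted p = 4.25e-06) and the ubiquitin hydrolase gene Uchl1 (−2.62, SE 0.393, adjusted p = 0.000352; −2.01 without gastrocnemius double KO 1) likewise had a lower log2 change in soleus. Slc2a3 (2.26, SE 0.250, adjusted p = 3.28e-06), the scavenger receptor gene Stab2 (1.86, SE 0.381, adjusted p = 0.0154, and 0.169 with only the compared groups in the fit) and the serine protease gene Htra1 (1.82, SE 0.266, adjusted p = 0.000262) had a higher one. Slc2a3 and Npr3 had fractional counts in 29 and 17 of the 32 libraries. The difference in the denervation and neuromuscular junction list passed as lower in soleus with the preset correlation (3.14e-05, and adjusted p = 0.0535 with an estimated correlation). It had 2 members lower and 0 higher over all genes and 4 lower adjusted over the list alone. Its mean was −0.02 and its median 0.13, with double KO 1 included. The list score of double KO 1 was 1.44 in soleus and 1.25 in gastrocnemius. In double KO 2, 3 and 4 it was −0.09 to 0.12 in soleus and 0.58 to 0.68 in gastrocnemius.

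Of the 137 genes, 56 had a higher and 81 a lower log2 change in soleus, and DESeq2 called 229. With the mouse as a block, which the shared animals of the muscles call for, 258 were called. With only the compared groups in the fit 31 were called and without the libraries in doubt 478. The count was 337 without soleus double KO 1, and 85, 81, 72 and 91 without gastrocnemius double KO 3, gastrocnemius double KO 4, gastrocnemius control 1 and soleus control 3. Slc25a30 (2.30, edgeR adjusted p = 0.0219) was lost without gastrocnemius double KO 3 or 4 or control 1 or without soleus control 2 (0.0541 to 0.0608), and its value was 2.95 without gastrocnemius double KO 1. It had fractional counts in 23 libraries. Tmem100 (1.94, adjusted p = 0.0334) was lost without gastrocnemius double KO 2, 3 or 4 or control 1 or 3, or soleus double KO 2 or 4 or control 1, 2 or 4 (0.0535 to 0.0940), and its value was 2.54 without soleus control 3. Both calls were also lost without the filter on low counts (0.0660 and 0.0650) and with only the compared groups in the fit (0.1097 and 0.220).

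**Figure D4:**
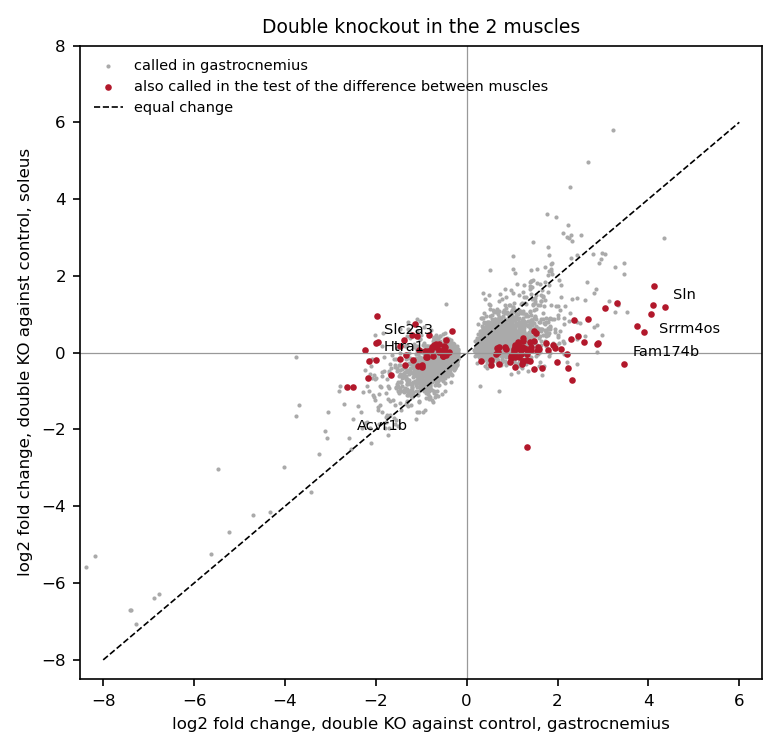
Log2 fold change of double KO against control in gastrocnemius (horizontal axis) and soleus (vertical axis) for the 3569 genes called in gastrocnemius and tested in both muscles; the dashed line marks equal change, and red points are the 123 genes also called for a difference between the muscles. Sln, Fam174b and Srrm4os lie below the dashed line.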

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

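Of the tests in this part, those of a wider spread in soleus by its slope and of reads shared between near-identical copies were set before their results were seen, and the tests of the slope without mouse 1, of linked variants, of a receptor response, of spread as the whole cause, of double KO mouse 1, of the cohort, of a library fault, of wrong labels and of other cell types were chosen after the result was seen.

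The calls in single knockouts lay near the targeted genes. Of 46 calls of genes other than the target in the 4 single-knockout comparisons, 78.3% lay within 20 Mb of their own targeted gene. These calls are not independent. All soleus calls were of genes also called in gastrocnemius of the same mice, and many near Tgfbr1 were copies that share reads. Genes there that were not called and had few shared reads held more unadjusted p under 0.05 than 95% of other windows of the genome in 3 of the 4 comparisons (11.7 and 11.4% in gastrocnemius and 6.25% in Acvr1b KO soleus against window medians of 4.96, 6.72 and 2.13%, and not in Tgfbr1 KO soleus, 2.78% against 2.60%), so variants carried along with the floxed alleles may account for the calls. The called genes near Tgfbr1 or on scaffolds mostly had reads shared with other genes: 96.2% of 26 had fractional counts in at least 16 libraries, against 39.8% of all tested genes, so a different number of copies in the strain of the floxed allele is a candidate explanation for these. The remaining 21.7% (6 genes on scaffolds and 4 elsewhere, each for Tgfbr1 KO in gastrocnemius) were called again in the double knockout in the same direction. The 6 on scaffolds fell (log2 change −6.765 to −1.664) with fractional counts in 30 to 32 libraries, like the copies near Tgfbr1. Their distance to Tgfbr1 was not measured, so they are not shown to lie away from it. The double knockout carries the same alleles and was compared with the same controls. This recall therefore cannot tell a response to the lost receptor from linked variants, and both stay open there.

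The double knockout gave 3673 calls in gastrocnemius and 131 in soleus. Over the 3569 genes called in gastrocnemius and tested in both muscles, the slope of the soleus on the gastrocnemius change was 0.530 (0.436 without mouse 1). A bootstrap over genes gave 0.493 to 0.566, a range that leaves out the spread between mice. Selection of these genes in gastrocnemius alone also lowers the slope, so part of the gap may come from the wider spread between soleus libraries. Spread as the whole cause is argued against by the 137 genes whose effects differed when tested directly. Double KO mouse 1 as the cause is argued against by the soleus count without it, which rose to 308 and stayed far below the gastrocnemius count. Of the 4 double-knockout animals, 0 have a number within the range of the other genotypes, so a later cohort cannot be told apart from the genotype in either muscle.

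Double KO mouse 1 stood apart in both muscles: its soleus library lay above all others by more than 1 on the log2 scale for 609 genes and below for 635 (97 and 117 in gastrocnemius), with Runx1 at 199 CPM (5.19 to 7.26 in the other double KO), Gadd45a at 903 CPM (10.4 to 13.1) and Perm1 at 17.4 CPM (541 to 582). A fault of 1 library is argued against by the correlation of this mouse's deviations across 816 genes between its muscles, 0.729 against at most 0.454 in any other mouse. These genes varied most in both muscles over libraries that include this mouse's, and deviations were taken from group means that include it. A wrongly labelled control or Tgfbr1 KO mouse is argued against by Acvr1b at 11.3 CPM in soleus and 22.01 in gastrocnemius, below every control and Tgfbr1 KO library (at least 26.1 and 64.0), which does not separate it from Acvr1b KO (11.9 to 15.5 and 21.7 to 25.3). A wrongly labelled Acvr1b KO mouse is argued against by the genes near Tgfbr1 that fell in gastrocnemius Tgfbr1 KO, whose median log2 CPM was −3.64 in its soleus and −4.22 in its gastrocnemius, against at least −1.92 and −1.86 in Acvr1b KO libraries. These genes had low levels and shared reads, and −4.22 is the floor for a gene without reads. Cells of all other types as the whole cause are argued against by 4 of 6 lists lying below 0 and below the other double-KO soleus libraries, but the macrophage score of 1.12 (−0.01 to 0.47 there) keeps more macrophages open, and an injury or a nerve lesion was not tested.

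Single libraries lay apart from the other 3 of their group by the gap test for 44 of 440 groups, where chance gives about 1 in 20 (22). In gastrocnemius control 1, the 10 largest genes took 33.5% of the counts (24.9 to 25.2% in the other controls), Myh4 measured 88720 CPM and Inhba 1.91 CPM. In gastrocnemius double KO 1, Myh1 measured 6298 CPM, and its scores were 0.27 for proteasome subunits, 0.24 for autophagy, −0.0692 for excitation-contraction coupling and 1.25 for denervation and neuromuscular junction. Gastrocnemius double KO 2 scored 0.0428 for mitochondrially encoded mRNAs and 0.24 for sex-linked genes, and double KO 3 0.61 for lymphocyte markers. Gastrocnemius Tgfbr1 KO 1 scored 0.22 for TGF-β family ligands, −0.25 for macrophage, −1.91 for neutrophil and 0.24 for nerve markers, and Tgfbr1 KO 4 −0.24 for tendon markers. Gastrocnemius Acvr1b KO 4 scored −0.11 for fatty acid genes and Acvr1b KO 2 1.12 for nerve markers.

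In soleus double KO 1, Tgfbr1 measured 57.6 CPM (15.7 to 18.6 in the other double KO) and Myh2 4815 CPM (13050 to 14550). The scores of the same library were 0.15 for IGF, Akt and mTOR signalling, 0.33 for cytosolic ribosomal proteins, 1.38 for ribosome biogenesis, −1.47 for slow-fibre genes, −0.87 for mitochondrial biogenesis, 1.44 for denervation and neuromuscular junction, 0.20 for the integrated stress response and −0.63 for smooth muscle. Soleus double KO 2 scored 1.98 for nerve markers. Soleus control 3 scored 0.12 for cytosolic ribosomal proteins, 0.0883 for the integrated stress response and 0.88 for nerve markers. Soleus Acvr1b KO 1 scored 0.38 for the respiratory chain, −0.36 for heat shock proteins, −0.17 for circadian genes, 0.51 for endothelial, −1.18 for fibroblast and −2.70 for tendon markers, and Acvr1b KO 3 0.27 for immediate early genes. In Tgfbr1 KO 1 of soleus Tgfbr1 measured 20.6 CPM, Tgfbr1 KO 3 scored 0.25 for heat shock proteins and −0.18 for smooth muscle, and Tgfbr1 KO 4 −0.28 for circadian genes and 2.21 for nerve markers.

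The double-knockout effect differed between soleus and gastrocnemius, in a direct test with edgeR, for 137 genes. By the rule these were Slc25a30 (2.30), Slc2a3 (2.26), Tmem100 (1.94), Stab2 (1.86) and Htra1 (1.82), with a higher log2 change in soleus, and Fam174b (−3.77), Sln (−3.18), Srrm4os (−3.06), Npr3 (−2.63) and Uchl1 (−2.62), with a lower one. Fractional counts were found in 29 of the 32 libraries for Slc2a3, 23 for Slc25a30 and 17 for Npr3. The call of Slc25a30 was lost without gastrocnemius double KO 3 (adjusted p = 0.0581), double KO 4 (0.0608) or control 1 (0.0570) or soleus control 2 (0.0541). That of Tmem100 was lost without gastrocnemius double KO 2 (0.0535), 3 (0.0909) or 4 (0.0940) or control 1 (0.0565) or 3 (0.0901), or without soleus double KO 2 (0.0869) or 4 (0.0583) or control 1 (0.0694), 2 (0.0718) or 4 (0.0887). With only the compared groups in the fit the calls of Slc25a30 (0.1097), Tmem100 (0.220) and Stab2 (0.169) were lost, and without the filter on low counts those of Slc25a30 (0.0660) and Tmem100 (0.0650). The difference moved by over 1.5-fold without gastrocnemius double KO 1 for Slc25a30 (2.95) and Uchl1 (−2.01) and without soleus control 3 for Tmem100 (2.54).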

How the results depend on the processing

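The fits without libraries in doubt, without nerve-rich libraries and without genes near the targeted genes were chosen after the data were seen; the other alternatives were planned. RLE size factors moved no count of called genes by over 1.5 times, and the edgeR counts of 0 (additivity in soleus, 614 at an unadjusted p under 0.05, and the differences of the Acvr1b KO and Tgfbr1 KO effects between muscles, 244 and 257) were 0 under each alternative run, DESeq2 included. Without genes near the targets, single-KO counts of 0 went with 720 (Acvr1b KO) and 989 (Tgfbr1 KO) genes at an unadjusted p under 0.05 in gastrocnemius and 329 and 388 in soleus, and that of double against Tgfbr1 KO in soleus with 1572. Where a count moved, the cause was not tested, except that fewer groups, libraries or genes entered some fits by construction.

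In gastrocnemius, Acvr1b KO against control (5) gave 26 by DESeq2, 2 with the replicate block, 3 with only the compared groups, 8 without libraries in doubt, 0 without genes near the targets and 3 to 9 with each library left out. Tgfbr1 KO (30) gave 57 by DESeq2, 100 without libraries in doubt, 0 without genes near the targets and 21 to 44 with each library left out. Double KO (3673) gave 2330 with only the compared groups and 2651 to 3872 with each library left out. Double against Acvr1b KO (2852) gave 4322 without libraries in doubt, and 2050 to 2942 with each library left out, and double against Tgfbr1 KO (2255) 1521 to 2095. Additivity (376) gave 734 by DESeq2, 146 with all 32 libraries in 1 fit, 792 without libraries in doubt and 232 to 548 with each library left out.

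In soleus, Acvr1b KO against control (4) gave 9 by DESeq2, 23 without libraries in doubt, 0 without genes near the targets, 1 without nerve-rich libraries and 3 to 5 with each library left out. Tgfbr1 KO (9) gave 19 by DESeq2, 17 with no filter, 34 without libraries in doubt, 0 without genes near the targets, 4 without nerve-rich libraries and 4 to 15 with each library left out. Double KO (131) gave 410 by DESeq2, 35 with only the compared groups, 499 without libraries in doubt, 80 without genes near the targets, 62 without nerve-rich libraries and 64 to 308 with each library left out. Double against Acvr1b KO (23) gave 152 by DESeq2, 15 with the replicate block, 0 with only the compared groups (1001 at an unadjusted p under 0.05), 13 without libraries in doubt, 2 without genes near the targets, 7 without nerve-rich libraries and 8 to 23 with each library left out. Double against Tgfbr1 KO (9) gave 84 by DESeq2, 2 with only the compared groups, 44 without libraries in doubt, 0 without genes near the targets, 4 without nerve-rich libraries and 4 to 11 with each library left out. The difference of the double-KO effect between muscles (137) gave 229 by DESeq2, 258 with the mouse as a block, 31 with only the compared groups, 478 without libraries in doubt and 72 to 337 with each library left out. The control muscles (7573) gave 6439 to 7268 with each library left out and 8533 with the mouse as a block, which changed no named call.

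Replicate numbers did not pair libraries across genotypes: over 24 pairs the median correlation of same-numbered libraries was 0.0013 in gastrocnemius and −0.0609 in soleus, and 1 and 2 libraries correlated best with their own number. With the replicate block 3631 genes were called for double KO in gastrocnemius and 100 in soleus.

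Of the values of named genes, DESeq2 ended 1 of 252 calls and gave 5 new ones, no filter ended 36 of 256, only the compared groups 69 of 244, the replicate block 24 of 226, and leaving out each library 338 of 2208. Without nerve-rich libraries 20 of 40 calls ended, without libraries in doubt 20 of 255, without genes near the targets 12 of 230 and with all 32 libraries in 1 fit 2 of 10; 0 called values changed direction under any alternative. The list of collagens in soleus Acvr1b KO changed direction without libraries in doubt (adjusted p = 0.00169) and ran from 2.24e-10 to 0.994 with each library left out, and that of cytosolic ribosomal proteins in soleus double against Acvr1b KO from 2.76e-11 to 0.668. Their calls in the reported direction were lost without Acvr1b KO 1, control 1 or control 3 for the first and without Acvr1b KO 1 or double KO 2, 3 or 4 for the second, and the cause was not tested. The counts were not thinned to lower depth. At the depth of these libraries edgeR recovered 47.8% of 67 simulated 1.5-fold changes in gastrocnemius and 26.9% of 67 in soleus. DESeq2 recovered 65.7% and 46.3% of them, but made 26 and 29 false calls against 4 and 9 by edgeR. The larger DESeq2 counts above may therefore hold more false calls.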

Other observations

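Of the tests in this part, the levels of genes near Tgfbr1 in groups other than those compared were chosen after the result was seen, and the others before.

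In the double-knockout gastrocnemius, single genes of further lists passed while these lists did not (camera adjusted p from 0.0821 to 0.834). Of 23 myogenic regulators 7 rose and 2 fell, of 31 proteasome subunits 3 rose and 0 fell (2 rose adjusted over the list alone; camera adjusted p = 0.0821), and of 25 autophagy genes 4 rose and 3 fell, with Atg12 at 0.51 (SE 0.080, edgeR adjusted p = 0.000283). Of 11 polyamine genes 1 rose and 3 fell (1 and 4 adjusted over the list alone): spermine synthase (Sms) rose by 0.63 (SE 0.100, adjusted p = 0.000293) and the S-adenosylmethionine decarboxylase gene Amd1 fell by 0.71 (SE 0.107, adjusted p = 0.000178). The mitochondrial folate enzyme gene Mthfd2, of the integrated stress response list, rose by 1.13 (SE 0.179, adjusted p = 0.000308). Of 34 collagen and fibrillar matrix genes 8 rose and 3 fell (8 and 4 adjusted over the list alone; camera adjusted p = 0.735). Of the adipocyte markers, of which 2 rose and 4 fell among 12 (3 and 5 adjusted over the list alone), Cidea rose by 1.61 (SE 0.346, adjusted p = 0.00330) and Plin4 fell by 1.10 (SE 0.145, adjusted p = 5.47e-05), and the immunoglobulin gene Ighm rose by 1.25 (SE 0.222, adjusted p = 0.000745).

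Between the muscles, the Tgfbr1 KO effect on the adipocyte list passed as higher in soleus only with the preset correlation (median 0.84, higher for 11 of 12 genes, 0 called by edgeR, camera adjusted p = 5.01e-10). It did not pass with an estimated correlation (adjusted p = 0.0884). Control muscles also differed in excitation-contraction coupling genes, of which 17 were lower and 1 higher in soleus (adjusted p = 0.204 with an estimated correlation), and in polyamine genes, of which 5 were lower and 2 higher (adjusted p = 0.027 with an estimated correlation), with a mean of −1.52 and a median of 2.4e-05. In soleus double KO, lymphocyte markers had a median of 0.93 (camera adjusted p = 0.00997, and adjusted p = 0.648 with an estimated correlation; 0.0647 without double KO 2).

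Each comparison was repeated on other splits of its libraries into groups of 4. In most comparisons only the real split, 1 of 35, called as many genes, which is the smallest share that 35 splits can give. In gastrocnemius these were Acvr1b KO (5 calls, highest other split 1), double KO (3673, 422), double against Acvr1b KO (2852, 6) and double against Tgfbr1 KO (2255, 80). In soleus they were Acvr1b KO (4, 1), Tgfbr1 KO (9, 0), double KO (131, 0), double against Acvr1b KO (23, 3) and double against Tgfbr1 KO (9, 1). The control muscles (7573, 230) and the difference of the double-KO effect between muscles (137, 0) were the others. For the control muscles, at most 5 genes were called in the 7 others among the 8 splits that part the 2 muscles of each mouse, and 230 where they do not. Because many comparisons were judged in this way, chance is not excluded for any single one. The Acvr1b KO calls include Acvr1b itself, and the soleus Tgfbr1 KO calls all lay in the repeated block with shared reads. For additivity in gastrocnemius, 1 of 100 splits drawn, the real one, gave as many calls (376, highest other 0). Those splits shuffled all 4 genotype labels and so mixed the double-KO libraries into the other groups. They cannot decide whether chance gives a departure from additivity where the genotypes differ. For gastrocnemius Tgfbr1 KO the number of calls did not set the real split apart: 3 of 35 splits gave as many genes as the real 30, and the highest gave 879. That split exchanged control 1 and Tgfbr1 KO 4, and 2 splits lay over 3 times above the real count, which points to a structure of these samples other than the genotype. The exchange left the remaining libraries of each genotype together. Mitochondrial genes held 13.93 to 25.99% of the counts on the side of control 1 and 10.35 to 13.88% on the other. Whether this share lies behind the calls was not tested. The splits do not use the place of the genes, and 20 of the 30 lay within 20 Mb of Tgfbr1. For 19 genes there, the median log2 CPM in the 2 groups not compared here, whose libraries entered the same fit, was −4.22 in each double KO and −1.86 to −0.89 in Acvr1b KO gastrocnemius. The value −4.22 is the floor that the prior count gives to a gene without reads. These genes were low in control gastrocnemius as well (means of 0.36 to 1.16 CPM) and had shared reads. Counts of 0 gave 100 of 100 splits for additivity in soleus (highest other 35) and 35 of 35 for the difference of the Acvr1b KO and of the Tgfbr1 KO effect between muscles (highest other 0 in each).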
